A study of Drosophila melanogaster with 384 samples.

How the data were processed

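Single cells were sorted into wells and amplified with SMART-Seq2 using 18 PCR cycles, a full-length protocol without molecular identifiers, per the labels' protocols. Larvae were reared at 29 °C and were 6 to 7 days old. The deposited table holds whole-number read counts per gene and cell that the authors made, and the values are not normalized, judging from cell totals that differ. The builds BDGP6 and dm6 are named in the submitters' processing notes, and the aligner, the counter and the use of strand are not given in the sources used here.

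The table has 384 cells and 14219 features, of which 11824 have a read. Of these features 13702 are gene IDs that matched a symbol in the gene name table and hold 94.8% of the reads. Another 206 gene IDs had no symbol there (4.70% of reads), and 311 were transcript IDs (0.505%). They stayed in the totals and are printed by ID only. The 21 rRNA pseudogenes held 4.13% of the control reads and 3.06% of the tumor reads and were not named. Genes of the fixed lists that matched no symbol, such as Imp, br, roX1, roX2 and Cyt-c-p, are in no list value. The IDs without a symbol can be retired ones, so such a gene may still be among the features printed by ID. Coordinates, exon overlaps and exonic lengths came from Ensembl release 115 on BDGP6.

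Groups, list genes, cell filters, alternatives and the rule for named genes were fixed before the data were examined. Cells with under 100000 reads or under 1000 genes were left out, 12 control wells and 7 tumor wells. No doublet caller was run, since the labels' protocols describe cells as sorted singly. The last well in sample order had the most genes on every plate (7758, 7653, 6976 and 7110 on plates 1 to 4) and was kept. Whether those wells held more than 1 cell is not given in the sources used here. Reads were summed over the kept cells of a group, 262976815 for control and 204489558 for tumor, and given as counts per 1000000 reads (CPM), and the ratio is tumor over control. A group with 0 reads was set to a floor of 3 reads over the group, and a share of 0 cells to 3 cells, which give the limits and the lower bounds of folds printed for counts of 0. Other sums carry exact Poisson intervals and other shares exact Clopper-Pearson intervals at 95%, which cover counting error only. For shares of cells and genes per cell each cell was thinned to 100000 reads. Each pool of brains is 1 sample, so no test, p-value or count of changed genes was made from cells.

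Gene lists numbered 31. A member was measured if the mean of both groups was at least 5 CPM, and a list's median was placed among 10000 random lists of the same size matched on expression in 20 bins. As a check chosen after seeing the data, lists were also matched on expression in 10 bins and exonic length in 5 bins, for the 6225 genes with a length. The genes named are brat, the 15 highest and 15 lowest ratios among genes with a read in at least 25% of the cells of the higher group that held a 2-fold ratio in the equal-weight mean over cells and in all 4 plate pairs, up to 4 members of each list by size of ratio (any member of a list of 8 or fewer), and genes of mitochondrial dynamics, lineage and timing chosen in advance. Complexes of the respiratory chain and the glutathione S-transferase family were chosen after their values were seen, as were the neighbors of Cpr64Ac that are named.

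Alternatives covered the weight of each cell, thinning, the scaling (TMM from edgeR, median of ratios, totals without abundant genes), cell filters, the median over cells, each plate left out and no minimum level. Added after seeing the data were type II-like cells, defined by at least 5 reads of at least 3 of pnt, btd, tll and Sp1, and totals of named genes. The steps were tested on simulated reads over 6443 genes of the tumor over control comparison. With 50 genes per size, simulated log2 ratios of 2 and -2 gave medians of 1.93 and -2.07, and those of 1 and -1 gave 0.96 and -1.05. A simulated list of 15 genes shifted by 1 came out at percentile 100, and an unchanged list at percentile 94.0. The simulated reads held no plate or pool effect and no slope with gene length. They test the arithmetic and not whether the real ratios are free of such effects. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16.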

Results

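The series holds single-cell RNA sequencing of neuroblasts, the neural stem cells of the fly brain, from central brains of Drosophila melanogaster third-instar larvae. Control cells came from larvae expressing a hairpin against mCherry, and tumor cells from larvae expressing a hairpin against brat, both driven in neuroblasts by insc-Gal4 together with membrane GFP. Brat is a translational repressor that restrains self-renewal in neuroblast daughters, and its loss gives brains filled with neuroblast-like cells. Green cells were sorted singly into 96-well plates, with 2 plates from a pool of 5 control brains (plates 1 and 2) and 2 from a pool of 3 tumor brains (plates 3 and 4). The question the study is known for is whether brat tumor neuroblasts differ from normal neuroblasts in oxidative metabolism and mitochondrial dynamics.

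After a minimum of 100000 reads and 1000 genes per cell, 89 and 91 cells of the control plates and 93 and 92 cells of the tumor plates were compared. The kept control cells held 126882 to 2329488 reads (median 1507070) and the kept tumor cells 185566 to 1960187 (median 1122670). Each group is 1 pool of brains and no label ties a cell to a brain, so there are no biological replicates, no test was made and no p-value is given. Intervals below are 95% intervals that cover counting error only. For levels in CPM they cover the counting of reads. The libraries carried no molecular identifiers, so reads include PCR copies and the error over molecules is not covered. Plates are nested in the groups, so plate and group cannot be told apart, and the 4 tumor plate over control plate pairs serve as the visible spread. The median absolute log2 ratio over genes was 0.40 between the control plates and 0.27 between the tumor plates, against 0.57 to 0.77 for the 4 pairs.

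At equal depth of 100000 reads, tumor cells showed fewer genes than control cells. The median was 3165 genes per tumor cell and 5013.5 per control cell, with 3183 and 3146.5 on the tumor plates and 4666 and 5324 on the control plates. Without thinning the medians were 3651 and 5801.5 genes. Summed over cells, the number of genes at 5 CPM (counts per 1000000 reads) or more was close, 6355 in the tumor pool and 6375 in the control pool.

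**Figure D1:**
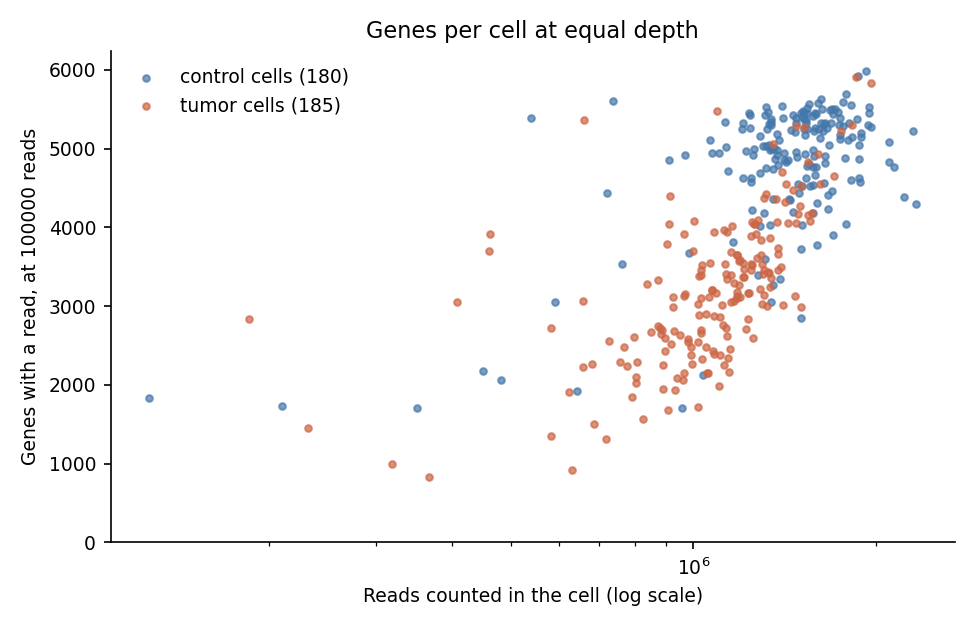
Each point is 1 kept cell, with the reads counted in it on a log axis and the genes with a read after thinning to 100000 reads on the vertical axis. Tumor cells (orange, median 3165) lie lower than control cells (blue, median 5013.5) with an overlap, and in both groups cells with fewer reads show fewer genes.

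The RNAi target brat (FBgn0010300, chromosome 2L, 19133816 to 19179758 in BDGP6) was lower in tumor cells. Its level was 343 CPM in the control pool and 88.1 CPM in the tumor pool, 3.89-fold lower. The control plates gave 312 CPM (interval 309 to 315) and 374 CPM (371 to 378), and the tumor plates 93.6 CPM (91.8 to 95.5) and 81.9 CPM (80.1 to 83.8). A brat read was seen in 99.4% of control cells (exact interval 96.9 to 100) and in 73.5% of tumor cells (66.5 to 79.7), or 100% and 81.1% without thinning. Exons of brat overlap CG17568 and Polr1D on the other strand, and whether counting used strand is not given in the sources used here.

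Tumor cells carried the transcripts of type II neuroblasts, the lineage class marked by pnt and lacking ase. All 4 type II markers were at least 2-fold higher, with a median log2 ratio of 5.67 (percentile 100 among 10000 random lists matched on expression). Over the plate pairs this median ran from 4.57 to 7.74, and the log2 ratio of Sp1 had a standard deviation of 2.26. The ETS factor pnt stood at 14.7 CPM in control and 949 CPM in tumor, Sp1 at 7.24 and 404, btd at 1.78 and 82.1, and the orphan receptor gene tll at 264 and 1784. A pnt read was found in 6.11% of control cells (3.1 to 10.7) and 89.2% of tumor cells (83.8 to 93.3), and the share with at least 5 pnt reads was 4.44% and 87.6%. An Sp1 read was found in 6.67% and 90.8% of cells and a btd read in 5.00% and 60.0%. In contrast, a tll read was common in both pools, in 73.3% of control and 90.3% of tumor cells. The type I factors went the other way in part: ase was 1.55-fold lower in tumor cells, and pros was at 465 CPM in control and 279 in tumor. In type II-like cells of both pools, of which control had 8, the log2 ratio of ase was 3.79. An ase read was seen in 86.7% of control cells and 35.1% of tumor cells. Without thinning these shares were 11.7% and 95.1% for pnt and 94.4% and 45.4% for ase. Over the 4 type I and progenitor genes the median was -0.04 (percentile 56.5), as Hey and dap were at 72.4 and 13.1 CPM in control and 106.6 and 35.7 CPM in tumor. In type II-like tumor cells alone, against every control cell, the log2 ratio of Hey was -6.87 and the log2 ratio of dap was -1.01.

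Self-renewal genes were higher as a group in tumor cells. Of 11 measured neuroblast identity genes, 7 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 1.25 (percentile 99.96, 1.23 to 1.62 over the plate pairs). SoxN stood at 238 CPM in control and 971 in tumor, the zinc finger gene klu at 403 and 1480, and dpn, a bHLH repressor that keeps neuroblasts self-renewing, at 920 and 1540. Notch target genes had a median of 1.94 (percentile 100), with 9 of 12 at least 2-fold higher. Among them E(spl)mbeta-HLH was at 177.9 and 2027 CPM and E(spl)m8-HLH at 317 and 2437 CPM. Among brat-linked factors, Myc, a growth regulator, was at 278 CPM in control and 1428 in tumor, whereas zld was at 260 and 336 (5 genes, median 0.74, percentile 93.4). The identity, Notch target and brat-linked lists all hold dpn and klu. E(spl)mgamma-HLH is an identity gene and a Notch target, and Myc is a Notch target and a brat-linked factor. The medians of these lists are therefore not separate results.

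**Figure D2:**
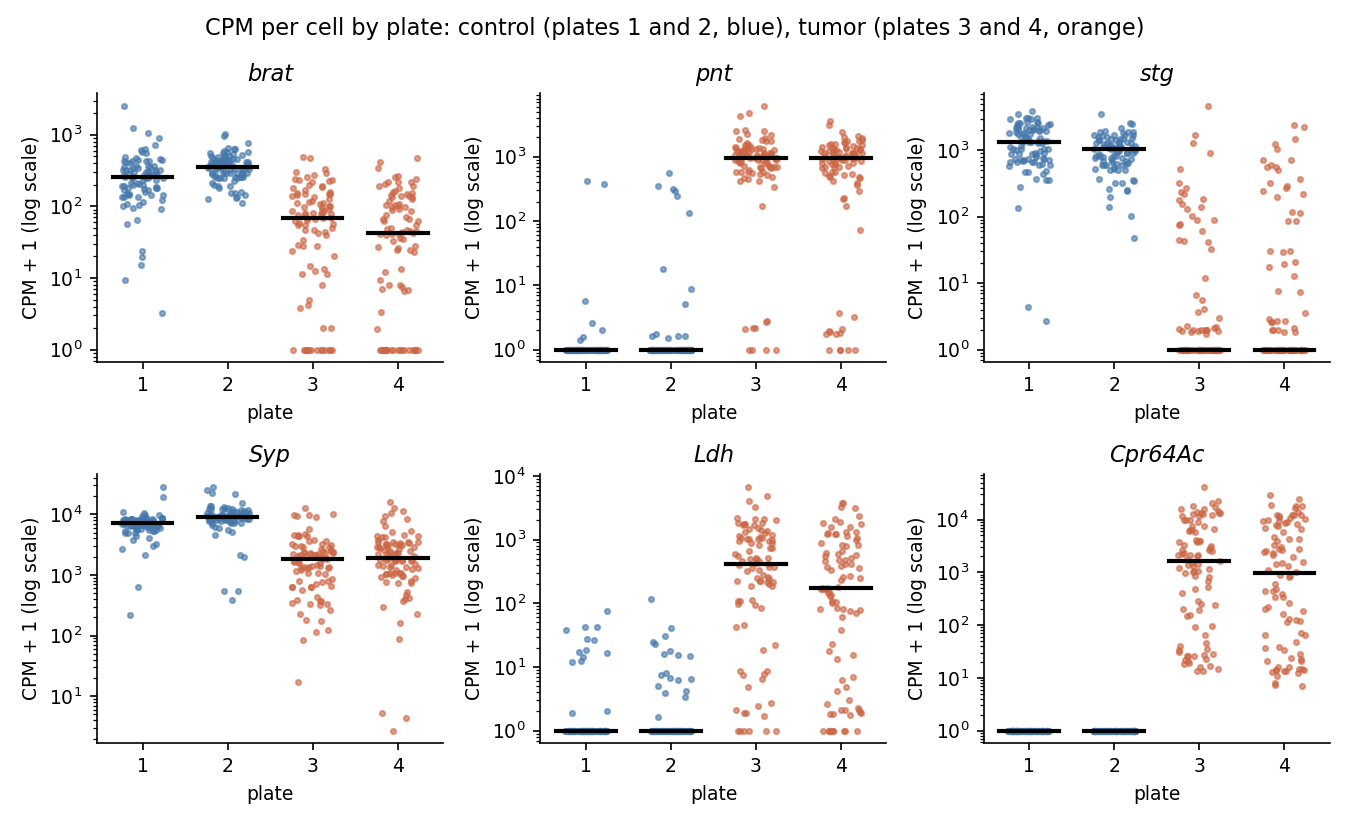
CPM plus 1 on a log axis for 6 genes in each kept cell, by plate, with control plates in blue and tumor plates in orange and a bar at the median of each plate. The genes pnt, Ldh and Cpr64Ac are higher and brat, stg and Syp lower on both tumor plates.

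Transcripts of glycolysis were higher in tumor cells and those of the nuclear-encoded respiratory chain were lower. All 12 measured glycolysis genes lay above the median of all genes and 7 were at least 2-fold higher, with a median log2 ratio of 1.08 (percentile 99.97, 0.91 to 1.36 over the plate pairs). Ldh, the lactate dehydrogenase gene, was at 3.71 CPM in control and 639 in tumor, 172.3-fold higher (pairs 7.18 to 7.62 in log2). In type II-like cells of both pools, of which control had 8, the log2 ratio of Ldh was 5.26, against 7.43 over all cells. Pfk, the gene of the committing step of glycolysis, was 4.78-fold higher (85.97 and 411 CPM), Gapdh1 3.97-fold and Gapdh2 3.72-fold. In the respiratory chain list 65 of 68 genes lay below the median of all genes and 35 were at least 2-fold lower, with a median of -1.01 (percentile 0.00, -1.34 to -0.64 over the plate pairs). Tumor plates 3 and 4 gave -1.34 and -1.15 against control plate 1, but -0.86 and -0.64 against control plate 2. The percentiles compare lists of genes and do not measure the spread between plates or pools. With the median over cells, where the median of all genes was -1.38, 22 of the 68 lay below it, and the list's median of -1.11 was below all 10000 random lists matched on expression.

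Complexes I, III and IV and ATP synthase each stood apart from random lists, in lists split after the values were seen, and complex II did not. The median log2 ratio was -1.02 over 33 genes of complex I, -0.82 over 4 of complex II, -1.32 over 9 of complex III, -1.24 over 9 of complex IV and -0.93 over 13 of ATP synthase. The lowest members were ND-B17 (344 CPM in control, 79.8 in tumor), UQCR-Q (1452 and 431), ND-B12 (579 and 174.4) and ND-ASHI (350 and 106.5). Mitochondrially encoded transcripts did not share this direction, with a median of 0.63 over 6 genes (percentile 90.3), mt:CoI at 3728 and 3579 CPM and mt:CoIII at 1539 and 2056 CPM. Respiratory chain genes are short, with a median exonic length of 862 bases against 2166 over all genes, and short genes were lower in the tumor pool in general. Random lists matched on both expression and length had a median of -0.56 (central 95% -0.77 to -0.29), and the list's value stayed below all 10000 of them. Against such lists complex I was at percentile 0.475, complex III at 0.39, complex IV at 0.72, ATP synthase at 2.36 and complex II, with 4 genes, at 15.35.

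**Figure D3:**
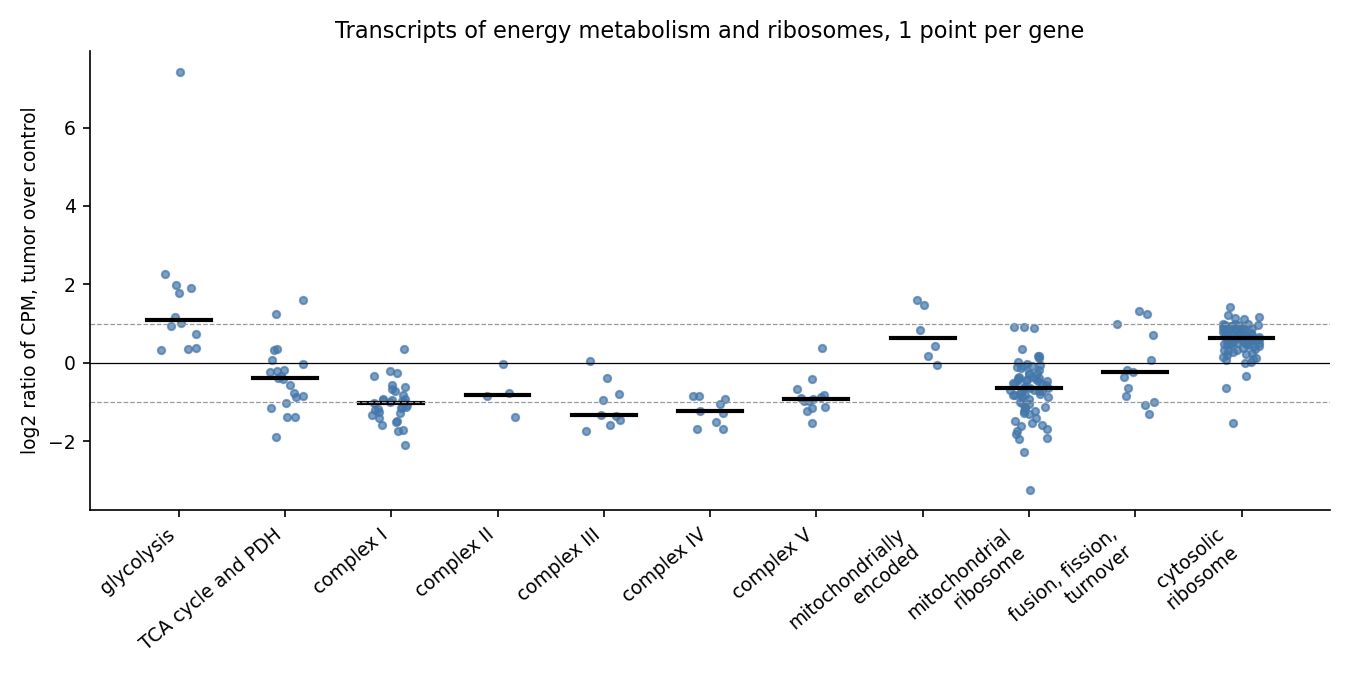
The log2 ratio of CPM, tumor over control, for each gene of 11 lists, with the list median as a black bar and dashed lines at 2-fold. Glycolysis (median 1.08) lies above 0 and the 5 respiratory complexes (-0.82 to -1.32) below it.

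The tricarboxylic acid cycle and pyruvate dehydrogenase list, which shares SdhA, SdhB, SdhC and SdhD with the respiratory chain list, did not stand apart from random lists. Its median was -0.38 over 21 genes (percentile 19.7). Within it CG5214, a component of 2-oxoglutarate dehydrogenase, was 3.71-fold lower, SdhD 2.63-fold lower and Scsalpha1 2.61-fold lower, while Pdha was at 22.6 CPM in control and 68.3 in tumor (log2 difference -0.94 by the median over cells). Mitochondrial fusion, fission and turnover genes also did not stand apart as a list (13 genes, median -0.25, percentile 33.5). The mitofusin gene Marf was at 76.1 CPM in control and 123.8 in tumor (log2 ratio -0.06 in type II-like cells of both pools), the inner membrane fusion gene Opa1 at 174.8 and 154.7, and the fission gene Drp1 at 282 and 134.1. The prohibitin genes Phb1 and Phb2 were 2.47-fold and 2.35-fold higher, and Chchd3, of the cristae organizing system, was 2.47-fold lower. NAD metabolism had a median of 0.72 over 8 genes (percentile 96.9), led by Sirt1 at 49.05 and 167.03 CPM, Naam at 9.56 and 26.3 (log2 difference -0.66 by the median over cells) and Naprt, which makes nicotinate mononucleotide, at 31.1 and 82.6.

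Cell cycle transcripts were lower in tumor cells. DNA replication and G1/S genes had a median of -0.84 over 23 genes (percentile 0.10, pairs -1.09 to -0.69), with 10 at least 2-fold lower. PCNA, the replication clamp, was at 1693 CPM in control and 409 in tumor, and RnrS, a subunit of ribonucleotide reductase, at 397 and 81.8. G2/M genes had a median of -0.78 over 28 genes (percentile 0.10), with 11 at least 2-fold lower. The mitotic phosphatase gene stg, which is in both cell cycle lists, was at 1253 and 151.8 CPM, 8.25-fold lower. The kinase gene aurA was at 114.5 and 29.6 CPM and CycB3 at 1067 and 332.

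Genes of the temporal program of neuroblasts differed in both directions. Of 10 measured genes 3 were at least 2-fold higher and 4 at least 2-fold lower, with a median of 0.31 (percentile 84.7). Imp and br, also on this list, matched no symbol, are not in these values and may be among the features printed by ID. The early factor chinmo was at 187.6 CPM in control and 741 in tumor, and lin-28 at 0.22 and 15.0. The late factor Syp, an RNA-binding protein, was at 8162 and 2517 CPM, and the ecdysone-induced Eip93F at 142.9 and 16.6. A chinmo read was seen in 95.6% of control cells and 97.8% of tumor cells (98.3% and 98.4% without thinning).

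**Figure D4:**
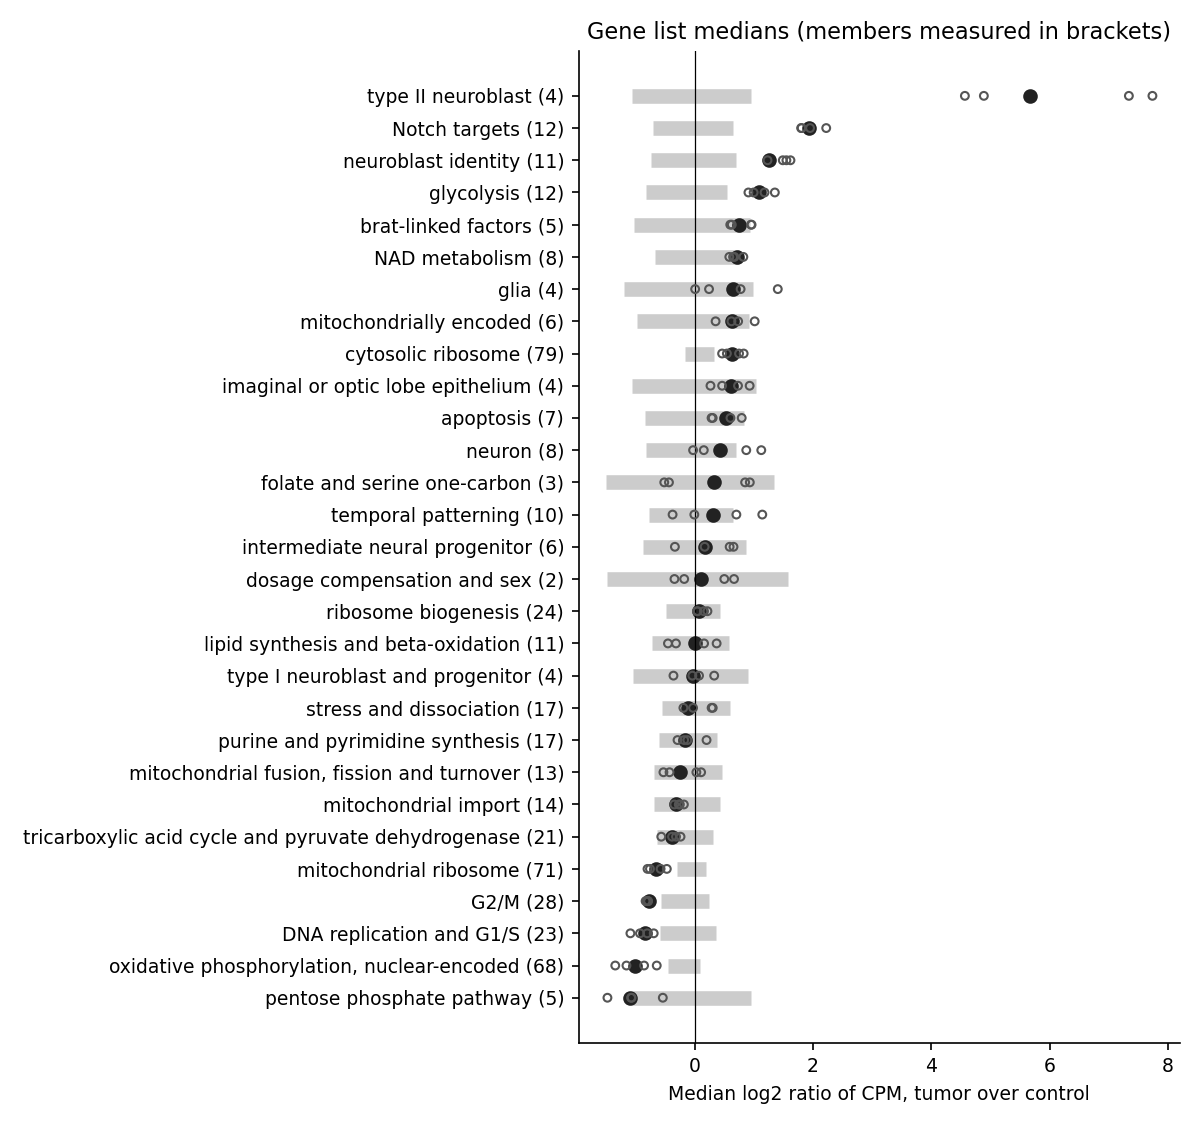
Median log2 ratio, tumor over control, of each gene list (filled points), the medians of the 4 plate pairs (open circles) and the central 95% of 10000 random lists matched on expression (gray bars). Type II markers, Notch targets, neuroblast identity, glycolysis and the cytosolic ribosome lie to the right of their gray bars, and the respiratory chain, the mitochondrial ribosome, the pentose phosphate pathway and both cell cycle lists to the left.

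The genes with the largest ratios, 15 in each direction, were picked among genes with at least a 2-fold difference in all 4 plate pairs. Cpr64Ac, a cuticle protein gene (FBgn0035512, chromosome 3L, 4211964 to 4212915), had 0 reads in control cells, which allows up to 0.0114 CPM, and 4210 CPM in tumor cells, at least 369087-fold higher against a floor of 3 reads over the group. Gadd45, a stress-induced gene, was at 0.22 and 256 CPM, Pvf2, a growth factor of the PDGF and VEGF family, at 0.21 and 23.1 CPM, and Oatp74D, an ecdysone importer, at 3.35 and 217 CPM. The glutathione S-transferase genes GstE1 (1.91 and 765 CPM), GstE6 (1.77 and 114.9) and GstT1 (0.71 and 43.6) were also in this set. CG30339, Marf1 (a gene unrelated to Marf), MFS3, Ldh, pnt and Sp1 were among the rest, with the feature FBgn0262735, for which the tables used gave no symbol (8.11 and 1425 CPM). Exons of GstE1 overlap GstE10, those of Pvf2 overlap Ugt307A1 and those of Marf1 a mobile element on the other strand, MFS3 overlaps lncRNA:CR45717 on its own strand, and reads may be shared among the related GstE genes.

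Among the lowest, the glutamate receptor gene GluRIIB (21.5 CPM in control) and the serpin gene Spn100A (20.4 CPM) had 0 tumor reads, at least 1468-fold and 1392-fold lower against the same floor of 3 reads. Eglp4, an aquaporin-like glycerol channel, was at 68.3 and 0.06 CPM, CG13023 at 242 and 3.42, CG2680 at 80.1 and 0.58, and CG5853 at 53.8 and 0.07. The piRNA pathway gene tej (15.9 and 0.07), the opsin gene Rh4 (11.5 and 0.08), Taf12L (40.0 and 0.30) and Cyt-c1L (7.61 and 0.17) were in this set as well. CG13692, CG43088, CG1998, CG17224 and CG11756 made up the rest, between 32.8-fold and 448-fold lower. Over the plate pairs their log2 ratios had standard deviations from 1.18 (CG13692) to 3.63 (CG11756). In type II-like cells of both pools, of which control had 8, the ratio was over 1.5 times smaller for 4 of the 15 highest genes and 4 of the 15 lowest, and over 1.5 times larger for 2 and 4. For another 5 and 2 genes a group had 0 reads there and the bound decides neither, and pnt and Sp1 are left out of these counts because they define the cells. The log2 ratio there was 3.98 for GstE6, 3.84 for GstT1, 3.67 for Marf1 and -2.75 for Rh4 (7 control reads). CG5853, CG2680 and CG13023 share exonic sequence with a gene on the other strand.

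**Figure D5:**
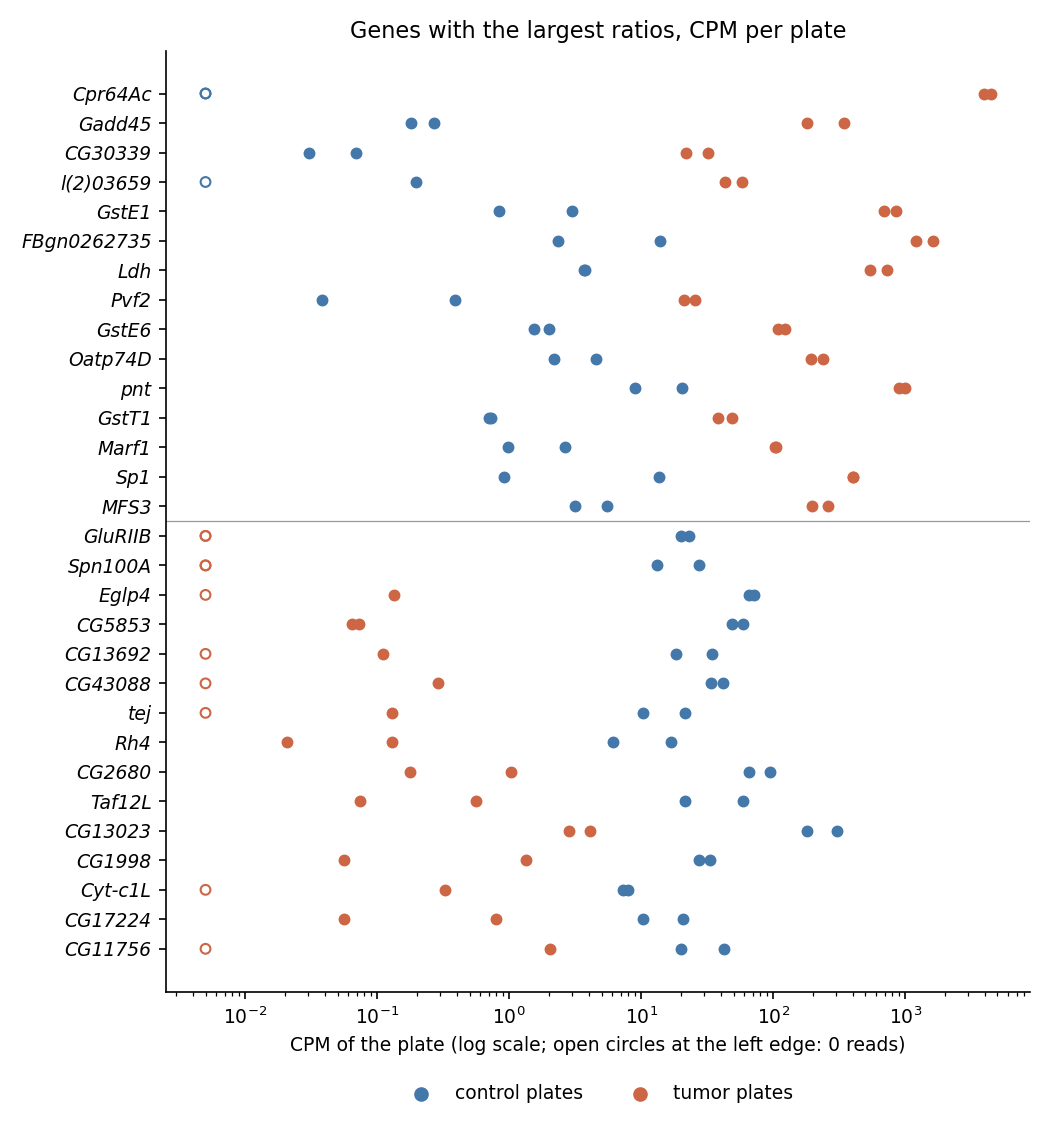
CPM of each plate on a log axis for the 15 genes with the highest and the 15 with the lowest tumor over control ratio, with control plates in blue, tumor plates in orange and open circles for plates with 0 reads. Both tumor plates lie on the same side of both control plates in every gene, which the rule for picking them requires.

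Markers of other cell types ranged from rare to present in most cells of both pools. A read of the neuronal gene elav was found in 81.1% of control cells and 77.3% of tumor cells (94.4% and 84.9% without thinning), of fne in 41.1% and 78.9% (71.1% and 84.9%) and of the glial list gene loco in 66.1% and 47.6% (84.4% and 58.9%). Syt1 was seen in 66.1% and 89.7% of cells (100% of both without thinning), and at least 5 of its reads at equal depth in 3.89% and 11.9%. A read of the glial factor repo was found in 1 control cell and in 0 tumor cells, which allows up to 1.62% of cells with a read at 100000 reads, and a read of the synaptic gene brp in 2 and 0. Without thinning the shares were 6.11% and 2.70% for repo and 5.00% and 3.78% for brp. Reads of Syx1A (98.3% and 90.8% of cells, or 98.9% and 94.1% without thinning), hth (86.7% and 89.2%, or 91.1% and 94.1%), shg, nrv2 and Eaat1 were also seen in most cells of both pools, with nrv2 at 448 CPM in control and 174.3 in tumor and Eaat1 at 89.7 and 146.9. The neuron list had a median of 0.43 over 8 genes (percentile 89.2), where fne was at 17.3 and 103.5 CPM and Cadps at 10.9 and 1.06. The glia list had a median of 0.64 over 4 genes (percentile 91.6) and the imaginal or optic lobe epithelium list 0.62 over 4 genes (percentile 88.3). No hemocyte gene reached 5 CPM. For intermediate neural progenitors the median was 0.18 over 6 genes (percentile 62.9), and an erm read was seen in 24.4% of control and 6.49% of tumor cells (30.0% and 10.3% without thinning).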

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

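The tests in this part of spilled reads and of type II identity were chosen only after the result was seen, and that of the neighborhood before its median was seen, while the neighbors named were picked after. The 7 tumor wells left out for low depth, which the main comparison did not use, held 300 Cpr64Ac reads in all, against 0 in the 12 control wells left out. On all 4 plates the 80th and 88th wells in sample order were among those left out. Whether these wells held a cell is not given in the sources used here. The level in the 7 tumor wells left out was 4145 CPM, close to the 4210 CPM of the kept tumor cells. What flagged it is a signal in wells outside the main comparison above the control wells. Reads spilled from other tumor wells would also give a level close to that of the pool.

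Cpr64Ac was the gene with the largest ratio, present in the tumor pool and at 0 reads in control cells. Type II identity was argued against: the 8 type II-like control cells had 0 reads among 11500342, which caps their level at 0.0062% of the tumor mean. That 0 followed from the 0 reads of all control cells, so the step adds the number and depth of such cells and no separate result. The 16 genes within 50 kb had a median log2 ratio of -0.22, under the bound of 1 set in advance as speaking against activation of the neighborhood, but that bound was set aside after the values were seen, because 3 genes were over 4-fold higher, 4 over 2-fold lower and 9 within 2-fold. With Cpr64Ad (0.01 and 6.55 CPM), Cpr64Ab (0 and 2.28) and ImpL2, a secreted insulin antagonist (44.3 and 1109), higher and VhaM9.7-a (64.6 and 2.38) lowest, activation of a shorter stretch cannot be told apart from activation of the gene alone, nor can reads spilled between tumor wells from expression in each cell, because the median kept cell held 48.8 times the Cpr64Ac reads of the median well left out but also 75.8 times its reads in all. A difference in strain or transgene insertion between the pools stays open and was not tested, as does the tumor itself, because each group is 1 pool.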

How the results depend on the processing

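Settings based on type II-like cells and on named genes alone were chosen after seeing the data, as were the minimum mean of 1 CPM for single genes here and the rule that a value of 0 is no turn of sign. No paired analysis was possible because each group is 1 pool of brains and no test was made. Over all settings the respiratory chain median stayed between -1.25 and -0.74 and mitochondrial fusion, fission and turnover between -0.48 and 0.07, within the spread of plate pairs, and glycolysis stayed between 0.95 and 1.33. With the median over cells of log2(CPM + 1), which puts the median of all genes at -1.38, brat was at -2.46, neuroblast identity 0.93, the tricarboxylic acid cycle -1.10, DNA replication -2.45 and G2/M -1.40, the respiratory chain at -1.11 lay above that median but below random lists matched on expression (median -0.36, percentile 0.00, a comparison added after seeing the data), and 19 of the 30 largest ratios kept 2-fold. Their 2-fold ratio in the equal-weight mean over cells and on single plates was set by how they were picked. In type II-like cells of both pools 4 of the 15 highest and 4 of the 15 lowest ratios were over 1.5 times smaller and 2 and 4 over 1.5 times larger, leaving out pnt and Sp1 and the 5 and 2 genes whose bound decides neither, with Ldh at 5.26 and Rh4 at -2.75, and with 1 control read of FBgn0262735 and 0 of MFS3. Neuroblast identity was 1.57 without plate 1 and 1.48 without plate 2, and the tricarboxylic acid cycle -0.55 without plate 1. Plate 1 also set the sign of the fusion list, at 0.07 without it. In type II-like cells of both pools, of which control has 8, neuroblast identity was 1.64, the tricarboxylic acid cycle -0.60, glycolysis 1.33, DNA replication -1.03 and G2/M -0.93. G2/M, whose plate pairs differ little, was -0.82 with equal cell weights, -0.80 thinned, -0.72 with TMM, -0.73 with median of ratios, -0.70 without abundant genes, -0.83 without cells of other types, -0.80 without plate 3, -0.74 without plate 4 and -0.85 for type II-like tumor cells against every control cell. Among genes at least 2-fold apart, signs turned for dap (-1.01) and nerfin-1 (-3.42) in that last setting, for Rbp6 (0.31) and crb (-0.62) in type II-like cells of both pools, and for Pdha (-0.94) and Naam (-0.66) with the median over cells, where both lay above the median of all genes; the cause was not tested. Of 2583 values of single genes under alternatives, 2307 moved less than the spread, 270 more and 6, of genes at least 2-fold apart, turned sign. The spread is the standard deviation over the 4 plate pairs and is wide for some genes (3.63 for CG11756). Several alternatives could hardly move a value, since scalings shift all genes alike and a filter that removes no cell changes nothing. These counts are therefore no measure of stability. For the 31 genes under 2-fold, 37 of their 527 values also had the opposite sign, in 22 of these genes. Examples are ase (3.79), Marf (-0.06) and pros (0.01) in type II-like cells of both pools. Hey (-6.87) and erm (-3.23) turned in type II-like tumor cells against every control cell. Of 252 shares of cells without thinning or at 5 reads or more, 55.95% left the interval of the main share. The neuroblast marker filter removed no cell. Depth limits single cells, thinned to 100000 reads, more than the pools, where 3 reads are 0.0114 CPM in control.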

Other observations

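The tests of gene length, and of type II cells for the respiratory chain and for genes per cell, were written before their result was seen; the others in this part, sequencing depth with its window of reads, pool-wide gene number and type II cells for glycolysis, after. Cytosolic ribosomal protein transcripts were higher, with 76 of 79 above the median of all genes (median 0.63, percentile 100), although they are as short as respiratory chain genes; RpL35 was at 825 CPM in control and 2222 in tumor, and RpS15Ab at 249 and 85.7. Ribosome biogenesis genes did not stand apart (24 genes, median 0.07, percentile 65.8). Mitochondrial ribosomal protein transcripts were lower (71 genes, median -0.65, percentile 0.00), led by mRpL51 at 97.9 and 10.4 CPM, but among lists matched on length as well they were at percentile 25.7. The small heat shock gene Hsp27 was at 8469 and 861 CPM and the Fos gene kay at 18.8 and 83.05, in a stress list that did not stand apart, with 5 genes at least 2-fold higher and 4 lower of 17 (median -0.12, percentile 31.5).

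Pentose phosphate genes had a median of -1.09 over 5 genes (percentile 2.23), with Zw, the first enzyme of the pathway, at 57.4 and 12.6 CPM and Pgd at 9.40 and 30.4. Purine and pyrimidine synthesis (17 genes, median -0.16, percentile 46.955), mitochondrial import (14, -0.32, 28.7), lipid synthesis and beta-oxidation (11, 0.01, 60.8), folate and serine one-carbon (3, 0.33, 72.7) and apoptosis (7, 0.53, 88.7) did not stand apart. Thymidylate synthase Ts was at 258 and 49.2 CPM, the carnitine palmitoyltransferase gene whd at 94.9 and 16.9, Shmt at 77.3 and 279 and the death gene grim at 7.61 and 38.6. Of 15 glutathione S-transferases 7 were at least 2-fold higher and 4 lower (median 0.46), with GstD9 at 63.1 and 777 CPM and GstS1 at 161.5 and 50.4.

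Genes tied to sex differed: Sxl, the female switch gene, was at 65.8 CPM in control and 199 in tumor, and msl-2, active in males, at 40.97 and 15.6 (list median 0.10, percentile 57.3). The median log2 ratio was 0.21 over 1091 genes of chromosome X and 0.61 over 54 genes of chromosome 4, against -0.12 to -0.04 on the other arms. The sex of the brains in either pool was not analysed here.

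Glycolysis transcripts were higher and respiratory chain transcripts lower in the tumor pool, and a share of type II cells of 84.9% there against 4.44% in control might account for it. In type II-like cells alone the glycolysis median was 1.33 (1.14 to 1.52 with each control cell left out). The respiratory chain median there was -0.74 (-0.82 to -0.66). These values argue against lineage share as the whole cause, with 8 control and 7 tumor cells just under the marker cut. Most type II-like control cells came from plate 2, so the choice of cells also changes the weight of the control plates. Over all cells without plate 1 the medians were 1.25 and -0.79. Gene length was argued against as the whole cause by percentiles of 99.99 and 0.00 among lists matched on expression and length. Lineage share and length were not tested together. The respiratory chain value of -0.74 in type II-like cells lies within the -0.77 to -0.29 of such lists over all cells. Both together therefore stay open for that list. The glycolysis value of 1.33 lies above its range of -0.75 to 0.45. Length still tracked the ratio, with medians of -0.50 in the shortest of 5 length classes and 0.49 in the longest, and control plate 2 over plate 1 showed the same slope (-0.32 to 0.44), while tumor plate 4 over plate 3 showed none (-0.01 in the shortest and -0.04 in the longest class, 0.09 to 0.11 between). That plates and pools differ in preparation stays open, as does an effect of the tumor, since plate and group cannot be told apart.

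Tumor cells showed fewer genes per cell. Depth was argued against, as the tumor median at equal depth was 3165 genes and the control lower quartile 4574, and among cells with 1200000 to 1600000 reads the medians were 3656.5 (60 tumor cells) and 4983 (98 control cells), a smaller gap. Fewer genes in the pool as a whole was argued against, since the tumor pool reached 99.7% of the control number at 5 CPM. The type II-like tumor cells had a median of 3346 genes, below the control lower quartile, but this cannot decide on a mix of cell classes. They are 84.9% of the tumor cells, whose upper quartile was 3795, so the outcome was fixed. The 8 type II-like control cells had 5413, so the gap was also seen within type II-like cells. A mix of other classes in the tumor pool stays open. Less RNA per cell, a lower capture on the tumor plates and larger differences between cells stay open and were not tested.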
